A study of Mus musculus with 2 samples.

How the data were processed

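Total RNA of the heart of female B6CASTF1/J mice was sequenced in 2 libraries. The samples share a donor label but carry separate animal numbers, and were taken as 2 animals. The labels list both as biological replicates of 1 group, so the tests compare libraries and no conditions. For each library the series holds a gene table and a transcript table from transcriptome alignments, and a second transcript table from 1 FASTQ file. Per the deposited listings both used mm10 with GENCODE M21. They are called the alignment-based and the read-based quantification here. The tools and their versions are not given in the sources used here; the column names are those that RSEM and kallisto write.

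Expected counts (alignment-based) and estimated counts (read-based) were deposited as reads assigned to each gene or transcript, not normalized, per the file headers. TPM, transcript abundance scaled to a fixed total, was computed by the authors over all entries, ERCC spike-ins included, per the file headers. The score columns hold the deposited lower and upper bounds of a credibility interval on TPM, whose level the file headers do not state. The percent column was deposited in the alignment-based transcript tables and gives each transcript's percentage of its gene, per the file headers.

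All 55536 genes were matched to the reference annotation by identifier. The 96 ERCC entries and 26248 tRNA entries were left out of gene totals. ERCC transcripts held 0.518% of the counts in replicate 1 and 0.544% in replicate 2, with 68 of 96 detected in each; counts to phiX were 0. The read-based transcript tables were summed to genes. They held 141767 transcripts against 141862, the 95 others lying on scaffolds. Read alignments and allele-specific signal were not analysed here.

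The choices that follow were made before the data were examined. Genes were detected at 1 TPM in both animals, and log2 ratios of TPM used a pseudocount of 0.1. There were 47 gene lists, 25 of cell types and 22 of processes, with 649 symbols, of which 5 were not found. Named genes were the 25 with the highest TPM outside mitochondrial, ribosomal and small RNA entries, all genes of pairs, the 3 highest of each list, all members of the X, Y, erythroid, immediate early and clock lists, the 15 largest ratios in each direction among differing genes with a mean count of at least 100, list members counted as differing, and the 5 highest genes with a differing leading transcript.

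Counts were scaled with TMM factors of edgeR 4.0.16 in R 4.3.3. Genes with a mean count of at least 10 were compared with a two-sided exact binomial test on rounded counts, with Benjamini-Hochberg adjustment, a threshold of 0.05, a minimum ratio of 2 and separate credibility intervals. Intervals of ratios are exact at 95% and cover counting error only; against counting noise alone the 2 libraries had a chi-square per degree of freedom of 12.67 over 15839 genes. For a list, the median log2 ratio was placed among 10000 random lists matched on mean count in 20 bins, with at least 3 members. The biological coefficient of variation came from edgeR with filterByExpr. Spike-ins with a mean count of at least 10 were compared with 20 matched genes each in 100000 permutations. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

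The steps that compare genes, lists and spread, and the coefficient of variation, were tested on simulated data; the other steps were not. For the comparison of genes between the animals (15839 genes, 200 changed per fold, credibility intervals not simulated), counting noise alone gave 2 of 200 called at 1.5-fold, 184 at 3-fold and 193 at 4-fold, with 3 of 15239 unchanged genes called. With the spread between the animals added, 8, 198 and 195 of 200 were called, and 50 of 15239 unchanged genes. For the list comparison (15839 genes), 7 of 100 unshifted lists of 10 genes and 8 of 100 of 20 genes stood apart, against 98 and 100 when shifted by 0.3. Log2 ratios were drawn there independently per gene, with the same spread at all counts. In the data the median absolute log2 ratio of genes was 0.35 at counts of 10 to 100 and 0.05 from 10000 on. These rates thus do not carry over to lists of low counts or of genes regulated together. For the spread comparison (900 genes), 2 of 100 simulations without added spread passed and 99 with 0.2 added. For the coefficient of variation (24818 genes), simulated 0.1 and 0.2 came back as 0.0986 and 0.197.

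Alternatives were the read-based values, posterior mean TPM, TPM rescaled to protein-coding nuclear genes (to all protein-coding genes for the mitochondrial share), other thresholds, filters, pseudocounts and spread measures, size factors of DESeq2 1.42.0, total counts, spike-in totals, omission of the credibility intervals, and each animal left out. Lists of liver, kidney, exocrine pancreas, small intestine, brain and skin genes, and of 2 arms of the clock, were added after the data were seen.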

Results

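The series measured total RNA, depleted of ribosomal RNA before sequencing, in the heart of 2 female B6CASTF1/J mice aged 25 days. B6CASTF1/J is a hybrid strain, the first generation of a cross between a laboratory strain and a wild-derived one. Both libraries were made from 300 ng of RNA with ERCC spike-in transcripts added, and the labels list them as biological replicates 1 and 2 of a single group. No condition was compared, so the values below describe the heart at this age and the spread between the 2 animals. Values are means ± SD over the 2 animals unless an animal is named, in TPM (transcript abundance scaled to a fixed total per library) of the alignment-based gene tables. Both samples carry 1 shared donor label but separate numbers for the animal; they are taken as 2 animals here, and every SD over animals rests on that. The estimated counts summed to 43190646 in replicate 1 and 42954475 in replicate 2.

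Genes of the contractile apparatus led the nuclear messenger RNAs in both hearts. Myh6, the adult cardiac myosin heavy chain, stood at 9642 ± 363 TPM (identifier ENSMUSG00000040752.16, chromosome 14, positions 54941921 to 54966927 of mm10). Myl2, the ventricular regulatory light chain, stood at 7908 ± 245 TPM, and Actc1, cardiac actin, at 6269 ± 13.7 TPM. Tpm1 (tropomyosin), Myl3 (essential light chain), Tnni3 and Tnnt2 (cardiac troponins I and T) followed at 5014 ± 31.4, 4638 ± 171, 4052 ± 118 and 3415 ± 56.4 TPM. Mb, the oxygen-binding protein myoglobin, stood at 7049 and 7034 TPM in replicates 1 and 2. All 28 genes of the sarcomere list were detected, that is, at or above 1 TPM in both animals, with a list median of 776 ± 19.5 TPM. Together they held 5.37% ± 0.104 of the TPM over all genes. Levels of single genes depended on the quantification: in the read-based tables Myl2 stood at 17270 TPM, above Myh6 at 8790 TPM, and Myl3, Tnni3 and Tnnt2 at 7076, 6270 and 6079 TPM. The share rested on what the total covered: it was 13.7% when only protein-coding nuclear genes were counted.

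Calcium cycling and excitation genes were expressed at graded levels, some as high as contractile genes. Atp2a2, the calcium pump of the sarcoplasmic reticulum, stood at 4673 ± 32.7 TPM and its inhibitor Pln at 2509 ± 163 TPM. Casq2, which stores calcium there, stood at 424 ± 3.31 TPM. Of the 16 calcium handling genes 15 were detected, with a median of 148 ± 1.76 TPM. All 15 ion channel genes were detected at a median of 19.9 ± 1.46 TPM, with the gap junction gene Gja1 at 172 ± 24.6 TPM, Abcc9 at 88.4 ± 3.47 TPM and Kcnip2 at 85.7 ± 2.89 TPM. The pacemaker and conduction list was lower, with 8 of 12 genes detected and a median of 3.16 ± 0.527 TPM. Its leading genes were Tbx5 at 12.6 ± 0.389 TPM and Gjc1 at 12.4 ± 1.67 TPM. In the list of natriuretic peptides and wall stress, Myh7 stood at 899 ± 14.1 TPM (1940 read-based), Nppa at 739 ± 142 TPM and Ankrd1 at 197 ± 54.9 TPM.

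Transcripts of oxidative metabolism made up a large part of both libraries. The 13 messenger RNAs of the mitochondrial genome held 14.0% ± 0.115 of all TPM, led by mt-Co1 at 35463 ± 1361 TPM, mt-Co3 at 17954 ± 355 TPM and mt-Atp6 at 17719 ± 841 TPM (29831 read-based). All 76 measured nuclear genes of oxidative phosphorylation were detected, with a median of 486 ± 0.0672 TPM (732 read-based). Among them Atp5b, a subunit of ATP synthase, stood at 3633 ± 72.8 TPM, Cox6b1 at 1838 ± 27.2 TPM (1104 read-based) and Cox4i1 at 1772 ± 30.1 TPM. All 25 genes of fatty acid oxidation were detected at a median of 259 ± 5.56 TPM, led by the fatty acid carrier Fabp3 at 1922 ± 107 TPM, the lipase Lpl at 1083 ± 53.1 TPM and Hadhb at 635 ± 0.410 TPM (1025 read-based). The citric acid cycle list had a median of 325 ± 4.86 TPM over 19 genes. The glycolysis list had a median of 218 ± 5.41 TPM over 20 genes, with Gapdh at 1857 ± 45.6 TPM (4343 read-based) and Aldoa at 1426 ± 7.22 TPM. The mitochondrial share is uncertain, because 4 pseudogene entries of mitochondrial sequence on chromosome 1 (Gm28661, Gm29216, Gm28437 and Gm10925) can take up the same reads. Gm28661 alone stood at 29604 ± 569 TPM, and the share was 20.7% with the 4 entries included. The read-based tables split these reads otherwise, with Gm29216 at 5205 TPM and Gm28437 at 21663 TPM.

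The adult or heart-enriched member exceeded its paralog in all 20 gene pairs fixed beforehand. Atp2a2 exceeded Atp2a1, the pump of fast skeletal muscle, by 13.54 ± 0.22 on the log2 scale of TPM + 0.1, and Tnni3 exceeded Tnni1, the fetal and slow form, by 12.04 ± 0.13. Myh6 exceeded Myh7 by 3.42 ± 0.08 (2.17 read-based). Actc1 exceeded skeletal actin Acta1 by 5.15 ± 0.24. Myl2 exceeded the atrial light chain Myl7 by 4.96 ± 0.28, and Myl3 exceeded Myl4 by 4.00 ± 0.26. For substrate use, the insulin-responsive transporter Slc2a4 exceeded Slc2a1 by 5.49 ± 0.15, Cpt1b exceeded Cpt1a by 3.06 ± 0.02 and Ckm exceeded Ckb by 5.71 ± 0.14. Margins were narrow for Hk2 over Hk1 at 1.08 ± 0.02, Pygm over Pygb at 1.27 ± 0.02, Cox7a1 over Cox7a2 at 1.29 ± 0.05 and Ldhb over Ldha at 1.68 ± 0.06. With a pseudocount of 1 in place of 0.1 the widest ratios fell, to 11.82 for Atp2a2 over Atp2a1, 11.09 for Tnni3 over Tnni1 and 8.58 (from 11.78) for Ryr2 over Ryr1, so their size rests on that choice. In the read-based tables the margin was 0.57 for Hk2 over Hk1 and 0.55 for Cox7a1 over Cox7a2. In each pair the ratio had 1 sign in both animals and its mean exceeded its SD. An exact sign-flip test over 2 animals cannot give a p below 0.5, so none was run.

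**Figure D1:**
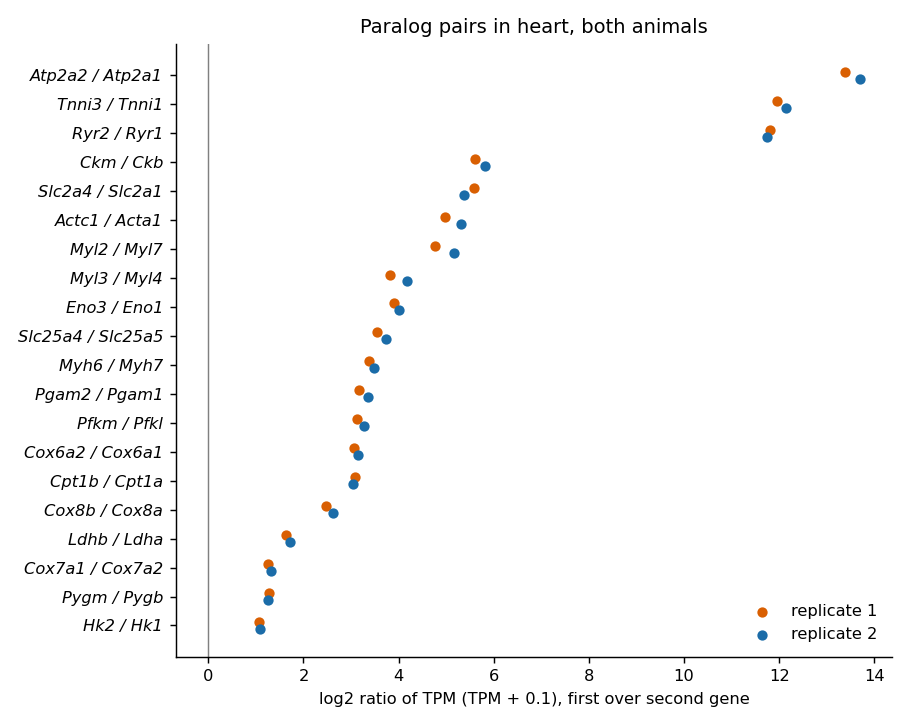
Log2 ratio of TPM (TPM + 0.1) of the first over the second gene of each of 20 pairs; 1 point per animal. All points lie to the right of 0, from Hk2 over Hk1 (1.08) to Atp2a2 over Atp2a1 (13.54).

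Marker genes of working heart muscle, blood, vessel and connective tissue cells were present in both hearts. The cardiomyocyte list had a median of 2962 ± 110 TPM (4750 read-based) and the erythroid list one of 508 ± 46.1 TPM (1191 read-based). Hemoglobin transcripts were abundant, with Hbb-bs at 3863 ± 34.6 TPM, Hba-a1 at 3352 ± 227 TPM and Hba-a2 at 3287 ± 92.6 TPM; the last 2 are near-identical copies whose reads the counting can split. The read-based tables gave Hbb-bs, Hba-a1 and Hba-a2 6922, 7543 and 2108 TPM. Fibroblast markers had a median of 64.0 ± 11.3 TPM (Gsn at 344 ± 35.6, Dcn at 159 ± 9.24, Col3a1 at 151 ± 38.8, or 230 read-based). Endothelial markers had a median of 32.3 ± 2.67 TPM (Fabp4 at 283 ± 44.4, Ly6c1 at 94.4 ± 30.0). Chamber markers of ventricle and atrium were both present, at medians of 39.0 ± 0.933 and 24.1 ± 2.54 TPM. Smooth muscle, pericyte, macrophage and endocardial lists had medians of 11.2 ± 3.85, 10.9 ± 1.44, 9.95 ± 1.73 and 8.34 ± 0.0106 TPM.

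Cells of the heart surface, lymph vessels and fat were marked at lower levels, and tissues next to the heart hardly at all. The lymphatic, mesothelial, white adipocyte and platelet lists had medians of 3.93 ± 0.516, 2.30, 1.81 ± 0.325 and 1.41 ± 0.106 TPM. The brown adipocyte list had a median of 10.8 ± 0.460 TPM, but its leading gene Cox8b, at 1011 ± 28.1 TPM (1667 read-based), is also a heart gene, and Ucp1 stood at 4.49 ± 1.90 TPM. In all, 15 of the 25 lists had a median of at least 1 TPM in both animals. The 10 below that level were T cell, B cell, neutrophil, mast cell, Schwann cell, neuron, fast skeletal muscle, cartilage and valve, thymus and lung epithelium, with medians from 0 to 0.555 TPM. No gene of the thymus or lung epithelium lists was detected in both animals, which speaks of levels under 1 TPM at this depth, not of absence.

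**Figure D2:**
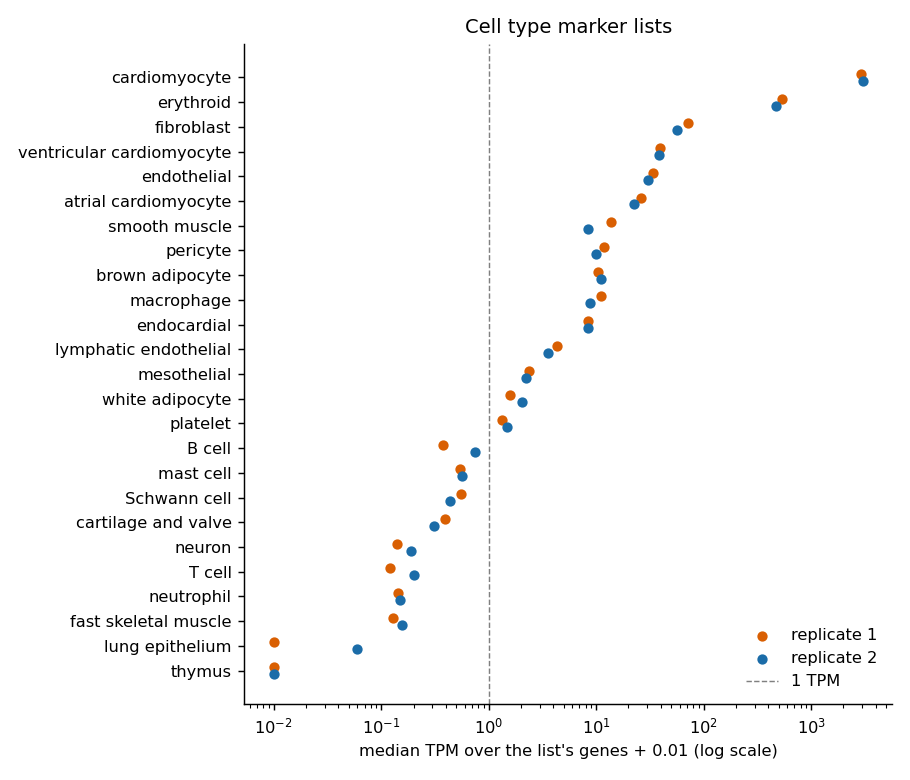
Median TPM over the genes of each cell type list, plus 0.01, on a log axis, with 1 point per animal and a dashed line at 1 TPM. The cardiomyocyte list (2962) and the erythroid list (508) lie highest, and the thymus list lies at 0 in both animals.

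Mitochondrial ribosomal RNAs and short structural RNAs held much of the TPM in the alignment-based tables. The mitochondrial ribosomal RNAs mt-Rnr2 and mt-Rnr1 stood at 131390 ± 3598 and 59917 ± 1760 TPM. Rn7s1 and Rn7s2, copies of the RNA of the signal recognition particle that share their reads, were each listed at 72772 ± 8597 TPM, and Rn7sk stood at 17235 ± 51.8 TPM. In the read-based tables Rn7s1 and Rn7s2 stood at 0.352 TPM and Rn7sk at 1.21 TPM. Malat1, a nuclear long RNA, stood at 1405 ± 474 TPM (691 read-based). Xist, expressed from the inactive X chromosome of females, stood at 24.3 and 17.8 TPM in replicates 1 and 2, with Ftx at 0.875 ± 0.191 (1.51 read-based) and Tsix at 0.21 ± 0.014 TPM. Of the 6 Y-linked genes, Ddx3y, Eif2s3y, Kdm5d, Zfy1 and Usp9y were at 0 in both animals, and Uty stood at 0.005 ± 0.007 TPM; read-based values were 0.571 TPM for Uty and 0.122 TPM for Kdm5d. Among 31 imprinted genes 20 were detected, led by Gnas at 464 ± 4.26, Igf2 at 55.3 ± 7.09 and Snrpn at 48.3 ± 1.95 TPM.

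Genes of the circadian clock spanned a wide range of levels at the time of collection, which the labels do not give. Dbp stood at 59.0 and 71.0 TPM in replicates 1 and 2, Tef at 51.1 ± 1.12, Nr1d1 at 46.2 ± 4.64, Nr1d2 at 41.9 ± 3.47 and Per1 at 22.2 ± 1.75 TPM. Clock stood at 10.5 and 8.25 TPM in replicates 1 and 2, Per3 at 7.65 and 7.78, and Per2 at 4.52 and 3.37 TPM. Arntl stood at 1.05 ± 0.389 TPM and Npas2 at 0.895 ± 0.092 TPM. Cell division genes were near the detection level, with 9 of 28 detected and a median of 0.565 ± 0.255 TPM; Mcm7 led at 4.08 ± 0.721 TPM (6.27 read-based). The interferon response list had a median of 1.28 ± 0.226 TPM. Ribosomal protein genes had a median of 168 ± 2.06 TPM over 88 genes (255 read-based), led by Rpl41 at 588 ± 29.0 TPM (1020 read-based). Over all classes 11947 genes were detected, of which 10985 were protein coding.

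For several of the most abundant heart genes, the 2 deposited quantifications named different leading transcripts. For Tnni3 the alignment-based tables placed Tnni3-201 first, at 51.3 and 52.7% of the gene in replicates 1 and 2, while the read-based tables placed the intron-retaining Tnni3-204 first. For Tnnt2 they placed Tnnt2-211 and Tnnt2-209 first, for Pln Pln-201 and Pln-204, for Mb Mb-202 and Mb-203. For Gapdh, the alignment-based tables placed Gapdh-208 first, annotated as a processed transcript, and the read-based ones the coding Gapdh-207. Over genes with several transcripts and at least 1 TPM, the leading transcript was the same by both quantifications in 75.1% ± 0.0764. Between the 2 animals it was the same in 89.5% of 10332 genes in the alignment-based tables and in 86.2% in the read-based tables.

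The 2 hearts differed in genes known to be induced by glucocorticoids or stress, higher in replicate 1, and in genes known from liver, higher in replicate 2. Entries of the classes TEC and sense intronic inside coding genes were higher in replicate 1 as well (median log2 ratio -0.41, replicate 2 over replicate 1, over 507). Zbtb16, a transcription factor induced by glucocorticoids, stood at 64.4 TPM in replicate 1 and 14.9 TPM in replicate 2, a ratio of scaled counts of 4.22 (95% exact interval 4.03 to 4.43). Fkbp5, a chaperone of the glucocorticoid receptor, was 3.47-fold higher in replicate 1 (3.11 to 3.87; chromosome 17). Pdk4, which restrains pyruvate oxidation on fasting, was 2.15-fold higher (2.09 to 2.20), the metallothionein Mt2 2.40-fold (2.04 to 2.83) and the nuclear RNA Neat1 2.53-fold (2.46 to 2.61). The inducible heat shock genes Hspa1a and Hspa1b, near-identical copies, were 3.48-fold (2.71 to 4.52) and 2.33-fold (1.84 to 2.97) higher.

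The larger set of genes higher in replicate 1 also held immediate early and cell division genes. Nr4a3 was 2.68-fold higher (2.19 to 3.32), Atf3 2.20-fold (1.57 to 3.14) and Fos 2.31-fold (1.49 to 3.66). Top2a, active in dividing cells, was 2.97-fold higher (2.19 to 4.10), Ccna2 4.97-fold (51 against 10 counts) and Kif11 2.19-fold (1.33 to 3.71). Further named genes were Fam107a (3.09-fold, 2.49 to 3.85) and the kinase gene Map3k6 (3.02-fold, 2.60 to 3.51). Zc3h11a (1048 against 0.55 counts) and Zbed6 (527 against 53.7) overlap on chromosome 1, and the read-based tables gave Zc3h11a the opposite direction, at 0.65 on the log2 scale, so both are uncertain. In replicate 2, Alb, the main plasma protein made by liver, had 907 counts against 2 in replicate 1, a ratio of 465 (128 to 3850). Apob, the lipoprotein carrier, had 256 counts against 2, a ratio of 131 (36.0 to 1091), and Cyp2e1 was 2.68-fold higher (2.21 to 3.27).

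Across 15839 genes tested, 120 were counted as differing, 73 higher in replicate 1 and 47 higher in replicate 2. The criteria were an adjusted p under 0.05 in the exact binomial test of the split of counts, two-sided with Benjamini-Hochberg adjustment, a ratio of at least 2 and no overlap of the deposited credibility intervals. At any ratio, 3147 genes had an adjusted p under 0.05. At a mean count of at least 100, 25 genes were left, 22 higher in replicate 1 and 3 in replicate 2. Without the genes of a liver list written after the data were seen, 93 were left, 73 and 20. The 20 still held relatives of listed genes, such as Serpina1c (34.4 counts in replicate 2 against 0), Serpina1d (34 against 2) and Cyp3a25 (32.7 against 0). These were named after their values were seen. The 20 are thus not a count of genes unrelated to liver. With spike-in scaling, which shifts every log2 ratio by -0.0991, 158 genes were counted, 112 and 46. The test and the intervals cover counting error in 2 libraries, treat reads as independent molecules and leave out the spread between animals, so they do not speak of conditions or other animals.

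**Figure D3:**
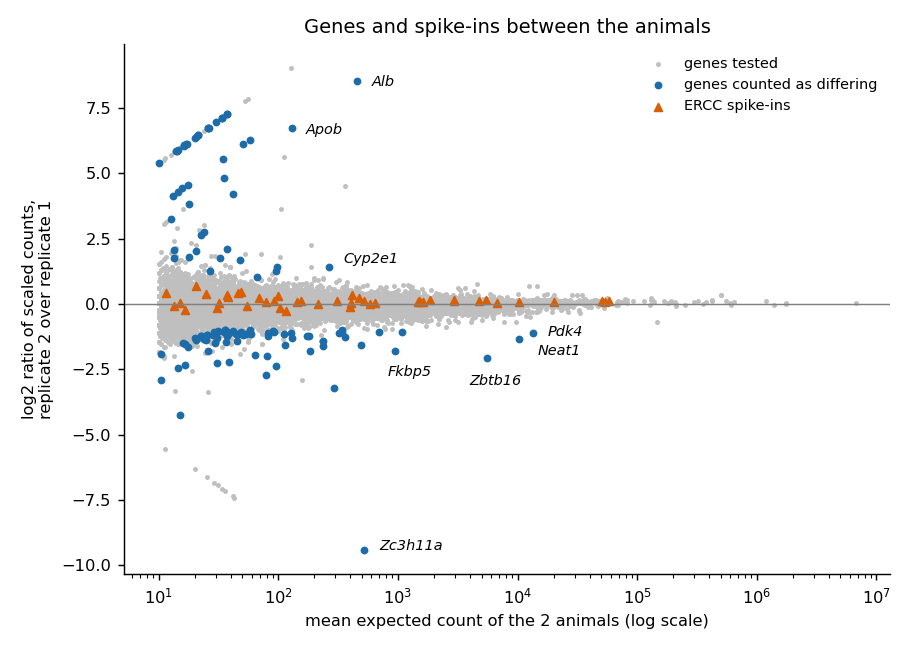
Log2 ratio of scaled counts (replicate 2 over replicate 1) against the mean expected count on a log axis, for 15839 genes (grey), the 120 genes counted as differing (blue) and the ERCC spike-ins with a mean count of at least 10 (orange triangles). Alb and Apob lie highest among the named genes, and Zbtb16, Fkbp5, Neat1 and Pdk4 lie below 0.

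Gene lists moved together between the hearts in both directions. All 13 genes of the glucocorticoid and fasting list were higher in replicate 1, with a median log2 ratio (replicate 2 over replicate 1) of -0.64, and 4 were counted as differing, both over all genes and adjusted over the list alone. Among them were Zbtb16 and Pdk4, and the ratio of Mt1 was -0.64. All 10 heat shock genes were higher in replicate 1 (median -0.47, 2 counted as differing by both adjustments), with Hspa8 at -0.36. Of 21 immediate early genes 20 were higher in replicate 1 (median -0.43, 3 counted as differing over all genes and adjusted over the list alone), and Ccn1 went the other way at 0.49. Of 27 cell division genes 25 were higher in replicate 1 (median -0.68, 3 counted as differing, also 3 adjusted over the list alone), on low levels in both animals; the median was -0.20 over the 14 genes with a mean count of at least 50 and -0.40 read-based.

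Supporting tissue and muscle lists parted as well. All 21 extracellular matrix genes were higher in replicate 1 (median -0.27; Sparc at -0.25, Col4a1 at -0.27), as were all 6 smooth muscle genes (-0.44), all 8 atrial genes (-0.20; Nppa at -0.31), 9 of 10 macrophage genes (-0.33), 8 of 9 fibroblast genes (-0.18), 10 of 11 endothelial genes (-0.18) and all 7 mesothelial genes (-0.27). In replicate 2, all 8 cardiomyocyte genes (median 0.12), 12 of 15 ion channel genes (0.13) and 4 of 6 ventricular genes (0.14) were higher. The sarcomere list (0.10), the mitochondrially encoded messenger RNAs (0.10), nuclear oxidative phosphorylation (0.10) and ribosomal proteins (0.05) were also higher in replicate 2 in scaled counts. Summed TPM went the other way for the mitochondrially encoded list (139133 in replicate 1, 137516 in replicate 2) and ribosomal proteins (14882 and 14516). It did not for the sarcomere list (52488 and 53941) and nuclear oxidative phosphorylation (47710 and 48214). Spike-in scaling shifts all medians alike, by -0.0991. With it, 4 of the lists outside the range of random lists went from above to below 0. The sarcomere list went from 0.0955 to -0.0036 and the mitochondrially encoded list from 0.0959 to -0.0032. Nuclear oxidative phosphorylation went from 0.0962 to -0.0029 and ribosomal proteins from 0.0485 to -0.0506. The sign of medians between 0 and the size of the shift thus rests on the scaling, while their place among random lists does not. The mitochondrially encoded list lay at the edge of the range of random lists and inside it in the read-based counts. All 5 B cell genes (0.94), all 4 platelet genes (0.70) and all 5 white adipocyte genes (0.45) were higher in replicate 2, at low levels. No gene of these muscle, stromal and blood lists was counted as differing.

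Medians of 21 of the 41 lists with at least 3 tested genes fell outside the central 95% of 10000 random lists of the same size matched on mean count, 11 on the side of replicate 1 and 10 on that of replicate 2. The nominal rate would place 2.05 of 41 outside; of simulated lists without a shift, 7 of 100 (10 genes) and 8 of 100 (20 genes) lay outside, and genes regulated together would raise this. In the read-based counts glycolysis (0.11), X inactivation (-0.41), nuclear and non-polyadenylated RNA (-0.17), lymphatic endothelial (-0.22) and brown adipocyte (0.32) lists also lay outside. The circadian clock list stayed inside that range at 0.02, and so did the erythroid list at -0.08, calcium handling at 0.07, fatty acid oxidation at 0.05, glycolysis at 0.07, the citric acid cycle at 0.07 and the imprinted list at -0.03. This describes the 2 libraries only, since genes are not independent replicates.

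**Figure D4:**
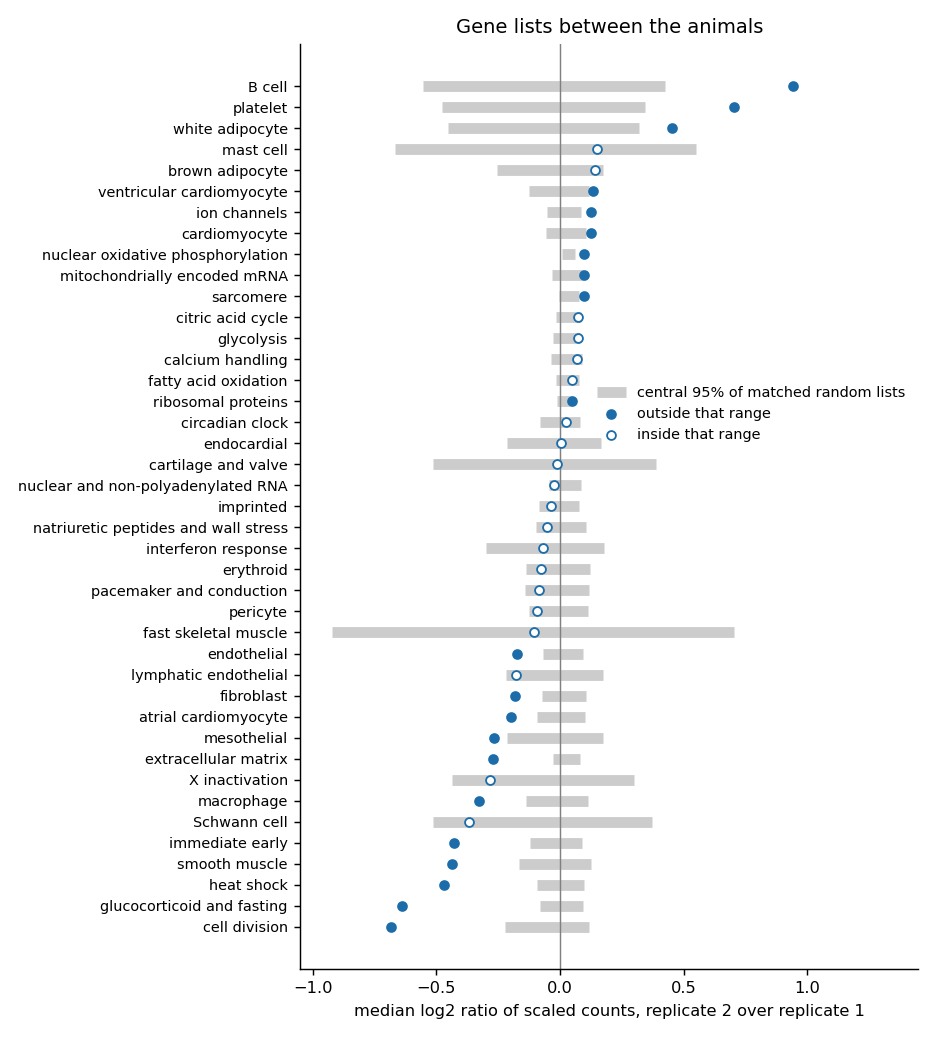
Median log2 ratio of scaled counts (replicate 2 over replicate 1) of each gene list with at least 3 tested genes; grey bars span the central 95% of 10000 matched random lists, filled points lie outside and open points inside. Cell division (-0.68) and glucocorticoid and fasting (-0.64) lie lowest with this filter and quantification, and the B cell list (0.94) lies highest.

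Over all genes, those of the groups above included, expression levels correlated between the hearts. Across 12301 genes with a mean of at least 1 TPM, log2(TPM + 0.1) correlated with Pearson's r = 0.976 and Spearman's rho = 0.985; this is a correlation across genes, which are not independent replicates. The common biological coefficient of variation of the animals was 9.01% over 15241 genes. The spread between the libraries was set beside that of spike-ins of like count, which carry technical spread only. The median absolute deviation of the log2 ratio was 0.14 for 900 matched genes and 0.06 for 45 spike-ins, a ratio of 2.47 (permutation test, two-sided, p = 0.0207). With the standard deviation in place of the median absolute deviation, the ratio was 3.45 and the permutation p was 0.0798. Because genes carry the difference between the animals as well, no conclusion is drawn from either ratio.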

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

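No test or alternative in this part was chosen after the result was seen. The entries for tRNA genes, which no comparison used, held a summed expected count of 4.9 in replicate 2 and 0 in replicate 1. It was singled out because it lies above the limit of 3 that a count of 0 allows. No explanation of it was weighed.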

How the results depend on the processing

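Of the alternatives, 5 were chosen after the data were seen: the mitochondrial share with the pseudogenes, the correlation after rescaling, and the runs without liver-list or without TEC and sense intronic genes. All 20 pairs kept their direction under every alternative, though 15 ratios and the levels of all 25 most abundant genes followed moved by more than the spread between animals in the read-based values, and 5 ratios with a pseudocount of 1. The cell type lists past the threshold numbered 15 to 17 of 25 and detected genes 11947 to 15311 (12175 to 12401 leaving out each animal). The sarcomere share was 7.44% in the read-based values and 13.7% after rescaling (5.29 to 5.44% by animal). The mitochondrial share was 16.1% read-based, 13.6% with posterior means, 26.2% after rescaling and 20.7% with the 4 pseudogenes (13.9 to 14.0% by animal). Both rescaled shares rest on a smaller total. The correlation was 0.989 with a pseudocount of 1, 0.982 without the filter, 0.978 read-based and 0.984 after rescaling. The coefficient of variation was 10.0025% without the filter and 9.11% read-based. Differing genes numbered 25 (3 higher in replicate 2, 22 in replicate 1) at a mean count of at least 100, where fewer were tested, 268 (115 and 153) without the credibility intervals and 309 (91 and 218) at 1.5-fold. They numbered 134 (47 and 87) with total counts, 158 (46 and 112) with spike-in totals, 129 (60 and 69) without the filter, 112 (47 and 65) read-based, 120 with DESeq2 factors, 93 (20 and 73) without liver-list genes and 98 (46 and 52) without TEC and sense intronic genes. Lists standing apart numbered 20 of 36 at a mean count of at least 50 and 25 of 41 read-based. The spread ratio was 3.45 with a permutation p of 0.0798 by standard deviation and 2.31 (p = 0.0302) at a count of at least 100. The same leading transcript was found in 74.1% at 10 TPM, 86.9% where it held at least 60% of the gene, and 75.0 to 75.1% by animal. Zc3h11a reversed to 0.65 in the read-based counts, and 3 of 29 differing genes followed singly were weaker there; of the list medians that of mitochondrially encoded messenger RNAs was weaker and 5 were stronger. Where not stated, the cause was not tested. With 2 animals, leaving 1 out gives no value for results that compare them. At low counts, depth limits the ratios: counting noise alone gave a median absolute log2 ratio of 0.24 at counts of 10 to 100 and 0.01 from 10000 on.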

Other observations

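Of the tests in this part, only that of the summed counts of 5 other tissues was chosen before its result was seen; the rest, and the added gene lists they use, were chosen after the differing genes had been seen. The series holds 1 group, so no explanation was tested against a condition.

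Entries of the annotation classes TEC and sense intronic were mostly lower in replicate 2 (390 of the 507 inside coding genes). The list of nuclear and non-polyadenylated RNA, which also holds mitochondrial ribosomal RNAs and Rn7s1, had a median log2 ratio (replicate 2 over replicate 1) of -0.02, with 9 of 19 genes higher in replicate 2, and one of -0.17, outside the range of random lists, in the read-based counts. Within it Malat1 stood at -0.69 and Neat1 at -1.34, and Rn7s1 at 0.33. Of the differing genes 90 of 13555 tested were protein coding (0.664%), 20 of 581 were of the annotation class TEC (3.44%), 6 of 327 lincRNA (1.83%) and 2 of 66 sense intronic (3.03%).

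Genes of liver were higher in replicate 2 as a set. The list of 58 genes was written before the test but after the differing genes had been seen, so its members are not independent of them. Of its 44 tested genes 41 were higher in replicate 2 and 27 were counted as differing, and the ratio of counts summed over the whole list was 1.26. Beyond the naming rule, and chosen after their values were seen, Apoa1 had 101 counts against 1, Serpina3k 114 against 1 and Ttr 80 against 4. Mat1a and Gc, chosen likewise, had 75 and 68 against 0. Their ratios were 25.7 and 23.3 with the count of 0 set to 3, which leaves out the error of the count in replicate 2. Among the abundant genes of the list, Trf stood at 15.3 TPM in replicate 1 and 15.6 TPM in replicate 2, and Alb at 0.03 and 13.4 TPM. In replicate 1, 12 of the 58 genes stood at 1 TPM or more, from a source that was not tested. Of the 58, 1 is in another list. All 27 genes of this list counted as differing were higher in replicate 2.

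RNA of liver, from tissue or from another library, is a hypothesis that the tables leave open. Of 32 tested liver genes under 1 TPM in replicate 1, 96.9% (31; exact 95% interval 83.8 to 99.9) were higher in replicate 2, against 44.7% of all 3542 genes chosen the same way. This lends it no weight of its own, since the list was written after the differing genes were seen. A split of reads between related genes particular to the alignment-based counts would be lost in the read-based ones. There the median log2 ratio of the 27 genes was 4.23 (range 1.27 to 8.81), so the difference does not rest on the alignment-based counts alone. A split shared by both quantifications of the same libraries is not excluded.

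RNA of several other tissues was tested on summed counts, where 0 of 5 lists were 2-fold higher: 331 and 306 in replicates 1 and 2 for kidney, 6 and 6 for exocrine pancreas, 637 and 591 for small intestine, 2257 and 2274 for brain, 132 and 130 for skin. That test decides nothing, as the liver list itself had a ratio of 1.26 on it. Over members under 1 TPM in replicate 1, the liver list had a ratio of 21.7 (18.1 to 26.1), from 127 counts against 2679. Alb and Apob, seen before the list was written, gave 907 and 256 of the 2679. Over members under 1 TPM in either replicate the liver ratio was 17.8. All 43135 genes chosen by replicate 1 had a ratio of 0.980 (0.973 to 0.987). For 3 of the 5 other lists the upper bound was under 2: kidney 0.949 (0.810 to 1.11), small intestine 1.09 (0.644 to 1.87) and skin 1.10 (0.779 to 1.57). Brain had 5.32 (3.09 to 9.74; 16 against 83 counts, of which Slc1a2 5 and 43, Gad1 4 and 23, both chosen after their values were seen), and pancreas 1.03 (0.274 to 3.84). Among fixed lists of tissues that dissection can carry along, lung epithelium had 0 counts against 13 (lower bound 3.13) and neuron 1.65 (1.24 to 2.21), while fast skeletal muscle had 1.07 (0.697 to 1.65), cartilage and valve 0.843 (0.693 to 1.02) and thymus 5 against 2 counts. RNA of several tissues thus cannot be told apart from RNA of liver alone: the lung list and the low members of the brain list were higher in replicate 2, on few counts and for brain mostly from Slc1a2 and Gad1, neither counted as differing, while the whole brain list was not, and those of kidney, small intestine and skin were not at 2-fold.

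For the glucocorticoid, immediate early and heat shock genes, a lower cardiomyocyte share in replicate 1 cannot be told apart from other causes. Of 8 other cell lists standing apart, 5 were higher in replicate 1, and the 3 higher in replicate 2 (medians of all 8 from -0.44 to 0.94) had levels of at most 1.81 TPM, too near the floor to exclude it. More unspliced or nuclear RNA in replicate 1 cannot be told apart from a response of those genes: 507 TEC and sense intronic genes within coding genes had a median log2 ratio of -0.41 (-0.45 to -0.34), and the 44 genes of the 3 lists one of -0.55 (-0.60 to -0.36). A different time of day cannot be told apart either. The medians of the Arntl arm (-0.24) and of the Per and Dbp arm (0.02) differed by -0.26 (bootstrap -0.68 to 0.28) over 14 genes. Bootstrap intervals here resample genes as if they were independent and leave out the spread between animals.

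Short RNAs were lower in the read-based tables, with Rn7sk at 1.21 TPM, Rpph1 at 3.38 TPM and Rmrp at 0 TPM. A fragment length that short transcripts cannot hold may explain this: across 28 spike-ins, the ratio of read-based to alignment-based counts correlated with length (Spearman 0.849, permutation p = 1e-05, the smallest possible). Near-identical copies would spare spike-ins, which have none, yet the median ratio was 32.4% lower in the 6 spike-ins under 600 bases (0.520) than in the 22 longer ones (0.769). Spike-ins thus lost counts with length without copies, but they cannot tell whether copies also took reads of Rn7s1 and Rn7s2. The shortest of the 28, which had mean counts of at least 100, had 505 bases, so Rn7sk lay outside their range. The loss of Rn7sk (135397 to 5 counts in replicate 1) was also far larger than that of the 28. Below that count minimum, the spike-in ERCC-00051 of 274 bases had 32 alignment-based counts in each replicate and 0 read-based. Other spike-ins of 273 or 274 bases had at most 3 alignment-based counts and 0 read-based. A complete loss was thus seen in a short spike-in without copies, on few counts and chosen after its values were seen.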
